A study of Homo sapiens with 5 samples.

How the data were processed

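RNA from 5 samples of 2 human lung adenocarcinoma cell lines was measured on Affymetrix GeneChip arrays, 1 array per sample, with 6 µg of total RNA per labelling per the labels' protocols. CL1-0 is the less invasive and CL1-5 the more invasive line of a pair. CL1-0 carried a scramble short hairpin RNA (shRNA; 1 array) or a KSRP shRNA (2 arrays, shKSRP-1 and shKSRP-2). CL1-5 carried the empty pEGFP vector (1 array) or EGFP-KSRP, a fusion of the green fluorescent protein to KSRP (1 array). KSRP is the KH-type splicing regulatory protein, encoded by KHSRP. Groups follow the sample labels; the series' design text places the KSRP shRNA in CL1-5, which the sample labels contradict. The labels do not say whether shKSRP-1 and shKSRP-2 are separate hairpins, cultures or hybridisations, so p-values measure only the spread between these samples, which may be technical.

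The authors deposited 1 table of log-scale values for 54675 probe sets, read here as log2; the values do not settle the log base, and every fold below rests on base 2. MAS5 is named, with no version or role, in the submitters' processing notes; the summarisation, scaling and centring steps are not given in the sources used here. Each probe set was centred within each line: the median of its 3 CL1-0 values was 0 for 54675 of 54675 probe sets, and its 2 CL1-5 values summed to 0 within 1e-05 for 54675. The table therefore holds no absolute signal and no level between the lines. Of the probe sets, 47.4% had at least 2 of the 3 CL1-0 values at exactly 0, and 26.8% had identical values in both shRNA arrays, against 3 probe sets with identical values in the CL1-5 arrays. A simulated median polish of 11 probes over arrays with no difference gave 83.7% such ties for 3 arrays and 0% identical values for 2 arrays. Array medians lay between -0.000792 and 0.000792. For arrays, their number limits the precision, and no signal over background can be read from centred values.

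Because of this centring, several steps of a design fixed before the data were examined could not be run as written. A filter on dim probe sets, the choice of the brightest probe set of a gene, quantile normalisation, offsets on a linear scale and the comparison of the CL1-5 with the CL1-0 control array all need an absolute level and were not run. A gene's value was the mean over its probe sets, which had been listed as an alternative, with no filter. limma's variance trend was left out of the primary fits, since the average level carries no information, and was run as an alternative. Random gene lists were matched on the number of probe sets per gene in place of expression.

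Of the probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 had none here and 62 were manufacturer's controls. Those with 1 symbol gave 19777 genes, 10523 of them with at least 2 probe sets. Symbols were updated through Entrez identifiers, of which 41037 probe sets had one in the reference table. Probe sets without a symbol are unnamed here and are reported as counts or as values without a name.

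KSRP shRNA was compared with scramble in CL1-0 by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. That fit has 1 residual degree of freedom, and the lone scramble array is assumed to vary like the shRNA arrays. A second limma fit over all 5 arrays coded KSRP status as -1 with shRNA, 0 in controls and 1 with EGFP-KSRP, with the cell line as a covariate and 2 residual degrees of freedom. CL1-5 has 1 array per group, so its differences have no replicate check and no p-value. Genes at least 2-fold apart, a log2 difference of 1, were counted in each array as a description. For 29 gene lists fixed with the rest of the design, camera was run with a preset inter-gene correlation of 0.01, and again with an estimated one; fry was an alternative. Each list's median was also placed among 10000 random lists. In CL1-0, 0 list members passed limma over all genes and 0 passed adjusted over the list alone. With KSRP status, 0 passed over all genes and 1, KHSRP, passed adjusted over the list alone. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the other steps.

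The fits were tested on simulated data. With the variance model estimated in CL1-0, limma called 0% of genes changed by 1, 2, 3 or 6 log2 units, so its count of 0 carries no information on how many genes differ. For KSRP status over both lines it called 38%, 86%, 88% and 96% of genes at these sizes, and 9 unchanged genes. There, 5.21% of unchanged genes had an unadjusted p under 0.05, against 218 of 19777 genes in the real fit. These shares may therefore not hold for the real values. With 3 simulated arrays against 3 limma called 100% of genes changed by 1 log2 unit. On simulated median-polished values with no difference, limma called 669 of 5000 probe sets, so ties alone can give calls. A simulated list of 24 genes moved by 1 log2 unit had an adjusted p of 5.45e-28 with the preset correlation and an adjusted p of 0.951 with an estimated correlation, so that alternative could not detect it here.

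The genes named were chosen by a rule fixed with the design: KHSRP, EGR3, FUBP1 and FUBP3; the 10 genes of each direction in CL1-0, filled by the smaller of the differences in both arrays where none passed; the 10 of each direction in CL1-5; the 8 of each direction with opposite differences in the lines; and up to 4 members of each list. Y-linked genes and unnamed LOC, orf, FAM and KIAA genes were skipped in the ranking. Members named with smaller differences, and genes in the closing section, were chosen after their values were seen.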

Results

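The series measured gene expression in CL1-0 cells depleted of KSRP and in CL1-5 cells given extra KSRP. KSRP binds AU-rich elements in messenger RNAs, recruits decay enzymes and promotes the maturation of some microRNAs. The data comprised 3 CL1-0 arrays (1 scramble, 2 KSRP shRNA) and 2 CL1-5 arrays (1 vector, 1 EGFP-KSRP). All values are log2 differences from the control array of the same line.

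KHSRP, the gene of KSRP, was lower than in the scramble control in both shRNA arrays, by -1.36 in shKSRP-1 and -1.58 in shKSRP-2. Its mean difference was -1.47 ± 0.159 (SE, n = 2 shRNA arrays against 1), with a limma adjusted p of 0.834. In CL1-5, KHSRP was higher by 1.19 with EGFP-KSRP. Its 4 probe sets differed. The probe set lowest in the shRNA arrays, at -2.20 and -2.93, differed by -0.03 with EGFP-KSRP, whereas another was lower by -1.06 and -1.12 and higher by 3.44. The remaining KHSRP probe sets showed -1.55, -2.16 and 0.93, and -0.61, -0.09 and 0.43. The direction of KHSRP followed the labels in all 3 treated arrays.

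**Figure D1:**
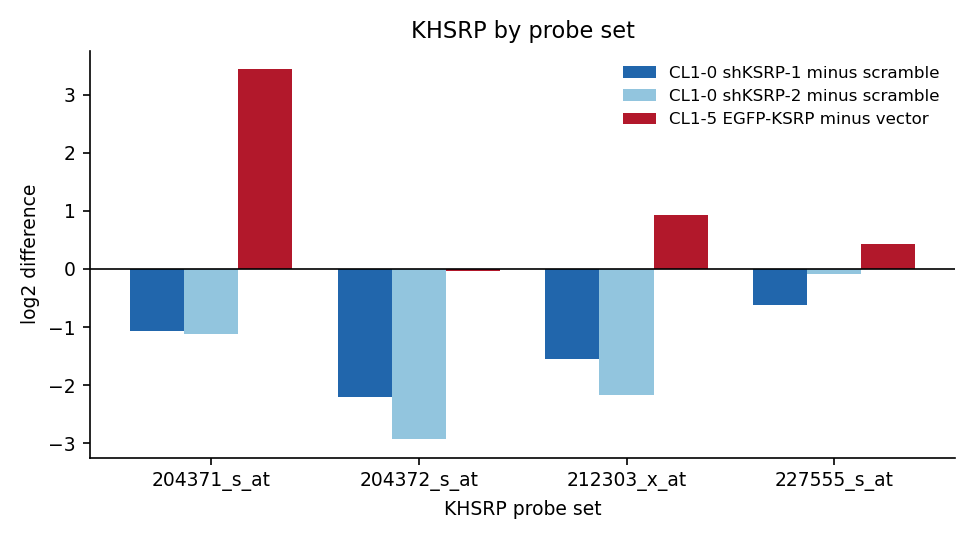
Log2 difference of each KHSRP probe set from the control array of its line, for the CL1-0 arrays shKSRP-1 and shKSRP-2 and the CL1-5 EGFP-KSRP array; each bar is 1 array against 1. The bars of the shRNA arrays lie below 0 at all 4 probe sets, and the EGFP-KSRP bars range from -0.03 to 3.44.

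The comparison of KSRP shRNA with scramble asks which transcripts differ when KSRP is depleted in CL1-0. EGR3, a zinc finger transcription factor of the immediate early class, ranked 1st among genes higher in both arrays by the smaller difference, at 2.53 in shKSRP-1 and 1.87 in shKSRP-2 (mean 2.20, SE 0.467, limma adjusted p = 0.980). Its relative EGR1 was higher by 1.55 and 0.999. DNAJB9, a chaperone of the endoplasmic reticulum, was higher by 1.71 and 1.33, and the cell cycle kinase gene WEE1 by 1.18 and 1.001. The neurofilament gene NEFH was lower, at -1.60 and -1.45, ahead of KHSRP in rank.

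The other genes higher in both arrays were GPR137C at 1.20 and 1.68, the coagulation inhibitor TFPI at 1.05 and 1.11, the dynamin DNM3 at 1.33 and 1.03, and VGLL3 at 1.02 and 1.13. ZFYVE26 was higher by 1.14 and 0.95, and GPR137B by 1.14 and 0.92. Lower in both arrays were NEXN-AS1 at -1.15 and -1.15, TMEM268 at -1.49 and -1.13, and the reductase gene DHRS2 at -3.15 and -0.94. BZW2 showed -1.44 and -0.88, and the small GTPase genes RAB26 and RAB8B showed -1.07 and -0.87, and -0.83 and -1.35. The histone gene H2BC11 was lower by -1.11 and -0.81, and SNAPC1, of the complex that binds the promoters of small nuclear RNA genes, by -0.81 and -2.16. The KSRP paralogs FUBP1 and FUBP3 differed between the arrays, at 0.24 and -0.45 for FUBP1 and 0.62 and -0.26 for FUBP3. The FUBP1 probe sets ranged from -0.90 to 1.38 in shKSRP-1 and from -1.23 to 0.28 in shKSRP-2. Those of FUBP3 were -0.21 and 1.44 in shKSRP-1, and both were lower in shKSRP-2, at -0.06 and -0.46.

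No gene passed limma: 0 of 19777 genes had an adjusted p under 0.05, the smallest adjusted p was 0.834, and 1095 genes had an unadjusted p under 0.05 against 989 by chance. That count moved with the treatment of tied values and was 423 of 17475 genes (874 by chance) without genes at 0 in all 3 CL1-0 arrays, and 173 of 16550 (828 by chance) without genes identical in the shRNA arrays, both chosen after seeing the data. The arrays showed 141 genes at least 2-fold higher and 295 lower in shKSRP-1, and 53 higher and 31 lower in shKSRP-2. Both arrays shared 7 higher genes (EGR3, DNAJB9, GPR137C, TFPI, DNM3, VGLL3 and WEE1) and 4 lower genes (NEFH, KHSRP, NEXN-AS1 and TMEM268). Independent lists would share 0.378 higher and 0.462 lower genes. Placing each gene's 3 values on the arrays at random, which keeps the shared control, gave on average 86.3 higher and 43.0 lower genes. The correlation of both differences across genes, which are not independent replicates, was 0.0857 with a covariance of 0.00611, against 0.502 and 0.0521 in that simulation. Random placing fixes the correlation near 0.502 whatever the values. It also puts the wider spread of shKSRP-1 on the shared control as often as that of the other arrays. The SD over probe sets was 0.387 in shKSRP-1, 0.133 in scramble and 0.173 in shKSRP-2. The simulation therefore cannot show whether the sharing lies below or above chance. The same limit holds for the list counts below with values placed at random. Between the shRNA arrays themselves, 600 genes were at least 2-fold apart, against 436 and 84 from scramble. With shKSRP-1 set against the other CL1-0 arrays, 319 genes were 2-fold apart from both, and with shKSRP-2 set against the others 53, against 11 for scramble.

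The shKSRP-1 array also differed from scramble by kind of probe set. Of the probe sets designed on RefSeq messenger RNA records, 0.793% were at least 2-fold higher and 2.44% lower. Of those designed on other records, 2.53% were higher and 1.72% lower, and of those with no gene symbol here 8.74% were higher and 0.452% lower. In shKSRP-2 these shares were all at most 0.482%.

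**Figure D2:**
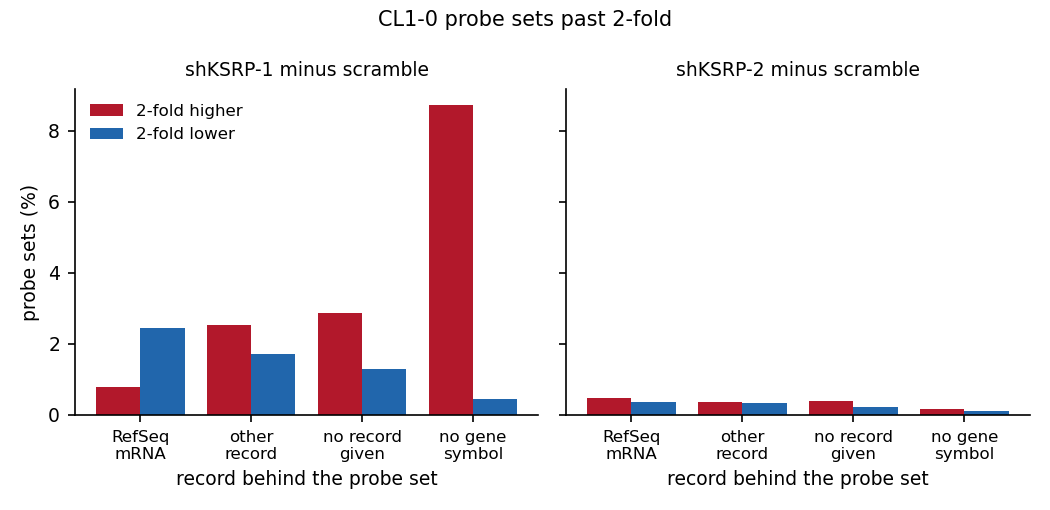
Share of probe sets at least 2-fold higher or lower than scramble, in percent, by the record the probe set was designed on, for shKSRP-1 (left) and shKSRP-2 (right), each 1 array against 1. In shKSRP-1 the share of higher probe sets runs from 0.793% on RefSeq messenger RNA records to 8.74% without a gene symbol.

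**Figure D3:**
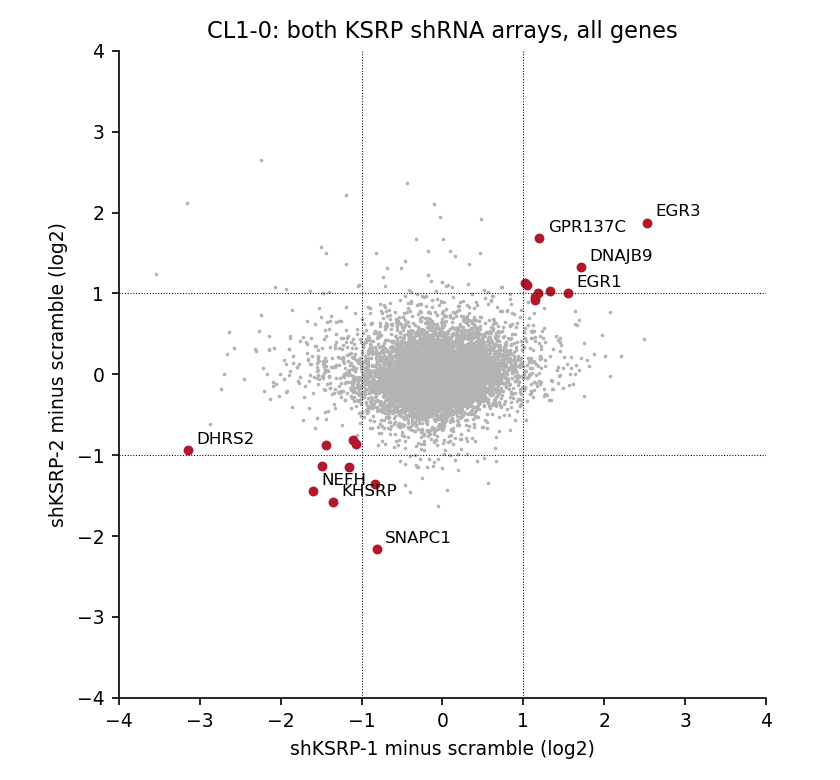
Log2 difference from the scramble array of every gene in CL1-0, shKSRP-1 on the horizontal and shKSRP-2 on the vertical axis; dotted lines mark 2-fold, and red points are the 20 genes named by rank. EGR3 lies farthest to the upper right at 2.53 and 1.87, and most other genes past 2-fold lie along 1 axis.

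Among the gene lists, the G2/M cell cycle genes were lower as a group: 19 of 24 were lower in both arrays and 0 were higher in both, with a list median of -0.25 in shKSRP-1 and -0.32 in shKSRP-2. CCNB1, the mitotic cyclin, showed -0.68 and -0.54, UBE2C -0.74 and -0.39, and TPX2 -0.40 and -0.66. Genes of oxidative phosphorylation were lower in both arrays for 20 of 24 members, with medians of -0.20 and -0.09, among them CYC1 at -0.88 and -0.42. The control probe sets of GAPDH were also lower in shKSRP-1, at -0.69 to -0.80, and those of ACTB at -0.35 to -0.52, against -0.13 to -0.17 and -0.01 to 0.01 in shKSRP-2. Over all genes, 25.4% were lower and 17.4% higher in both arrays. Both differences share the scramble array, so a deviation of that array alone gives a list of co-regulated genes the same sign in both. With each gene's 3 values placed on the arrays at random, 8 members of either list would be lower in both. Of the G2/M genes, 16 were also lower in shKSRP-2 than in both other arrays, and of the oxidative phosphorylation genes 20 were lower in shKSRP-1 than in both others. camera with the preset correlation gave an adjusted p of 4.27e-06 for G2/M and 0.00493 for oxidative phosphorylation. With an estimated correlation, a setting that also missed a simulated moved list, the adjusted p was 0.998 for both.

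Immediate early genes, which respond to growth factor signals, were higher in both arrays for 13 of 26 members and lower for 2 (medians 0.12 and 0.28; camera adjusted p = 0.000654, and adjusted p = 0.998 with an estimated correlation). Besides EGR3 and EGR1, KLF10 was higher by 0.89 and 0.74 and JUN by 1.11 and 0.52. Genes of microRNA biogenesis had a median of 0.26 in shKSRP-1 and -0.0227 in shKSRP-2, with 7 of 18 higher in both arrays, LIN28B at 0.84 and 0.60 among them; camera gave an adjusted p of 0.0151, and an adjusted p of 0.998 with an estimated correlation. Cholesterol synthesis genes were higher in both arrays for 8 of 15 members, led by INSIG1 at 1.06 and 0.89 (medians 0.15 and 0.01; camera adjusted p = 0.0195, and 0.998 as the adjusted p with an estimated correlation). The cholesterol call ended when probe sets ending in _x_at were left out (adjusted p = 0.0535). Values placed at random would have 8 immediate early genes, 6 microRNA biogenesis genes and 4.67 cholesterol synthesis genes higher in both arrays. These lists passed with the preset correlation alone, and 0 passed with fry. The same camera test called 4 lists when shKSRP-1 took the place of the scramble array as the lone array, and 3 when shKSRP-2 did, so the number of lists does not set the KSRP grouping apart. Of the 5 lists, microRNA biogenesis and cholesterol synthesis were called again with shKSRP-1 as the lone array, and G2/M with shKSRP-2. Immediate early genes and oxidative phosphorylation were called in neither. The missing call does not set oxidative phosphorylation apart, since 20 of its 24 genes were lower in shKSRP-1 than in both other arrays. Restricted to probe sets designed on RefSeq messenger RNA records, chosen after seeing the data, 3 lists passed: G2/M, oxidative phosphorylation and immediate early genes.

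The other lists did not pass camera in CL1-0 over all genes. The messenger RNAs reported to be bound by KSRP, taken as background, had medians of 0.00 and 0.05 (camera adjusted p = 0.165). Of these, 10 of 27 were higher in both arrays and 5 were lower. ZFP36 was higher by 0.77 and 0.48. EGR3, EGR1, JUN and FOS, which had the largest or near largest values, are also on the immediate early list. The bound messenger RNAs are therefore not separate evidence from that list. Targets of the let-7 microRNA had medians of 0.00 and 0.19 (adjusted p = 0.118), with ARID3A at 1.06 and 0.61. Both lists passed when genes at 0 in all 3 CL1-0 arrays were left out, an alternative chosen after seeing the data (adjusted p = 0.0455 for the bound messenger RNAs and 0.0260 for let-7 targets); with an estimated correlation the adjusted p was then 0.999 for both. That filter selects genes by the difference itself, and took the bound messenger RNAs from 27 to 24 by leaving out IL1B, MYOG and IFNA1. The AU-rich element binding proteins and decay factors had medians of 0.06 and -0.07, and DCP2, a decapping enzyme, was at 0.91 and 0.33. Genes of G1/S had medians of -0.07 and -0.21, with CDT1 at -0.48 and -0.55. Epithelial markers had medians of -0.04 and 0.04, mesenchymal markers -0.04 and 0.01, and matrix proteases and inhibitors -0.08 and 0.05. E-cadherin, encoded by CDH1, was at -0.56 and -0.34, and the protease inhibitor TIMP1 at 1.01 and 0.53. Other members of these lists went the other way, EPCAM at 0.40 and 0.36 and SERPINE2 at -0.55 and -0.87. Leukocyte markers had medians of 0.00 and 0.00, endothelial markers -0.0053 and 0.00, and fibroblast and smooth muscle markers -0.02 and 0.02.

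The medians of 15 of the 29 lists were below 0 in shKSRP-1 and above 0 in shKSRP-2. The contrasts were largest for the unfolded protein and amino acid response (-0.47 and 0.05), type I interferon genes (-0.15 and 0.09), and hypoxia and glycolysis genes (-0.21 and 0.03). Others among the 15 were integrins and laminins (-0.13 and 0.06), antigen presentation (-0.06 and 0.08), p53 targets (-0.04 and 0.09), NRF2 and xenobiotic enzymes (-0.17 and 0.02), neuronal and neuroendocrine markers (-0.12 and 0.02) and housekeeping genes (-0.08 and 0.02). The immunoproteasome genes PSMB8 and PSMB9 showed -1.23 and 0.37, and -1.18 and 0.45, whereas PSMB10, another, showed 0.07 and -0.35. GADD45A, a p53 target, was at -1.34 and -0.23, and CDKN1A, another, at 0.21 and 0.89. NF-kB inflammatory cytokines had medians of -0.07 and 0.00, Wnt/beta-catenin targets -0.09 and 0.00, TGF-beta targets -0.0011 and 0.10, ribosomal proteins 0.02 and -0.0026, and lung epithelial lineage genes 0.00 and 0.00. Apart from let-7 targets and messenger RNAs bound by KSRP, the lists that did not pass had adjusted p values of 0.387 or more. Among these, camera's direction was opposite to the mean or median in several, such as the unfolded protein and amino acid response (up, with a mean of -0.22).

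**Figure D4:**
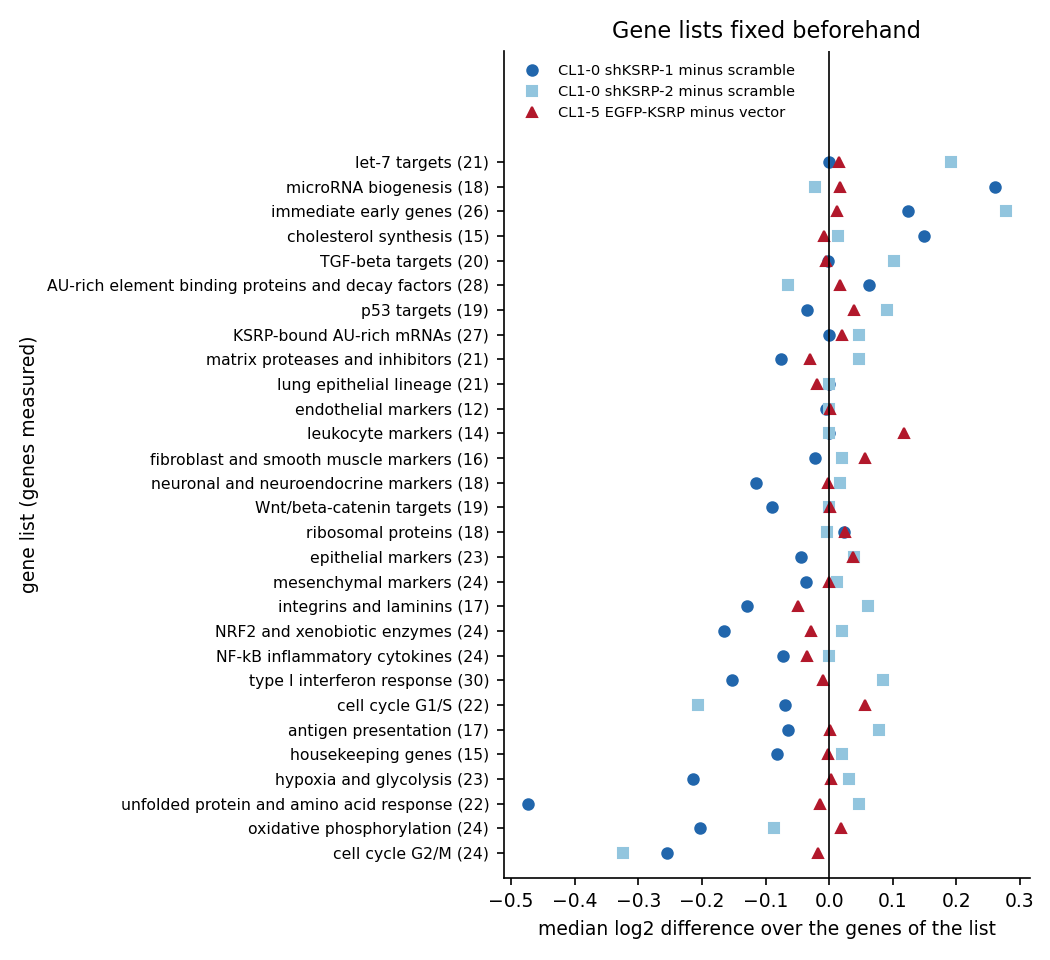
Median log2 difference over the measured genes of each of the 29 lists, ordered by the mean CL1-0 difference, for shKSRP-1 and shKSRP-2 against scramble and for EGFP-KSRP against vector; each point is 1 array against 1. The G2/M list has the lowest mean CL1-0 difference, with -0.25 and -0.32 in the shRNA arrays and -0.02 in CL1-5.

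The comparison of EGFP-KSRP with vector asks the reverse question in CL1-5, with 1 array each and no test. Besides KHSRP at 1.19, RAP1A, a small GTPase gene, was higher by 2.56, and no other gene reached 2-fold in either direction. The RAP1A value came from 2 of its 4 probe sets, at 4.70 and 5.65, while the other 2 differed by -0.09 and -0.02. EGR3 differed by 0.12, and EGR1 was higher by 0.60. Next in size were the lipid transporter gene ABCA12 at 0.86, EDARADD at 0.82, CHIAP2 at 0.81, GNMT at 0.74, SPAG17 at 0.73, FLJ13224 at 0.67, LINC01293 at 0.66 and the interferon gene IFNB1 at 0.64. The lowest were the potassium channel genes KCNK13 at -0.74, KCNJ14 at -0.69 and KCNK17 at -0.60, with APOD at -0.69, TAFA4 at -0.69, FBXL9P at -0.62, LINC01096 at -0.61, DEFA5 at -0.61, LINC01992 at -0.59 and LINC00622 at -0.59.

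Across genes, the CL1-5 difference had an SD of 0.131, against 0.339 and 0.210 in the CL1-0 arrays, and its 1st and 99th percentiles were -0.34 and 0.36. Leukocyte markers had a median of 0.12, at the 99.95th percentile of random lists, with 8 of 14 higher and 6 lower. CD14 was at 0.63, CSF1R at 0.44 and CD79A at 0.40, against -0.18 for LYZ and -0.15 for CD3E. Without probe sets ending in _x_at the leukocyte median was 0.02. G1/S genes were at 0.06 (98.0th percentile) and fibroblast markers at 0.06 (98.5th percentile). The G2/M list stood at -0.02 (20.2th percentile), immediate early genes at 0.01 (65.2th percentile) and messenger RNAs bound by KSRP at 0.02 (74.3th percentile). The medians of the 29 lists lay between -0.05, for integrins and laminins, and 0.12. Without probe sets ending in _x_at, the G1/S list had the largest median, at 0.06.

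The last comparison asks which genes moved oppositely with loss and gain of KSRP. KHSRP ranked 1st of 19777 genes by p in the fit over both lines, with a coefficient of 1.35 per step of KSRP status (limma adjusted p = 0.985), and it was the 1 list member that passed adjusted over the list alone. It was also the 1 gene at least 2-fold apart in opposite directions in both shRNA arrays and in CL1-5, but it is the gene that the shRNA and the construct changed. Without KHSRP, 0 genes were 2-fold apart in opposite directions, against 0.000152 by independent lists, and 0 in the same direction. Higher in both shRNA arrays and lower with EGFP-KSRP were ZPLD1 (0.40, 0.52 and -0.41), XNDC1N (1.09, 0.44 and -0.41), ADAMTS6, a matrix protease (0.97, 0.42 and -0.36), and TM4SF18, SPOCK1, POTEM, BACH2 and GPR137C. The reverse order was seen, besides KHSRP, in LINC03086 (-0.49, -0.40 and 0.35), PCP4 (-0.52, -0.51 and 0.32) and SPARCL1 (-0.75, -0.82 and 0.30), and in LRRC63, LINC01694, MAP3K5-AS1 and SMKR1. Apart from KHSRP, these genes were picked by their signs in the same data, with no count expected by chance. Their CL1-5 values, between -0.41 and 0.35, lay near or inside the 1st and 99th percentiles of all genes, -0.34 and 0.36. An opposite response to KSRP is not shown for them. No gene passed limma (0 of 19777, 218 with an unadjusted p under 0.05 against 989 by chance). The CL1-0 and CL1-5 differences had a correlation across genes of -0.0396 (Spearman -0.0433).

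With KSRP status, camera gave G2/M genes higher (adjusted p = 0.000471), oxidative phosphorylation higher (0.00382), immediate early genes lower (0.00382) and microRNA biogenesis lower (0.0363). With an estimated correlation the adjusted p was 0.978 for each of these lists, and with fry the adjusted p was 0.991 for each. Fewer lists passed camera on probe sets designed on RefSeq records. The medians of these lists in CL1-5 alone were -0.02, 0.02, 0.01 and 0.02. Only the oxidative phosphorylation median had the direction of its call there, so the other calls did not come from a matching shift in CL1-5. The next lowest adjusted p was 0.128, for cholesterol synthesis. Without shKSRP-1 the microRNA biogenesis call ended, and without shKSRP-2 those of G2/M and immediate early genes ended.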

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

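The tests in this part were chosen after the results were seen. No group held 4 to 10 arrays, so arrays were not tested for standing apart from their group. The values below come from probe sets with no gene symbol here, which the comparisons of genes do not use.

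Among them, 1 probe set was higher by 8.39 in CL1-5 EGFP-KSRP than in vector, and another was higher by 1.34. Of 11721 probe sets with no symbol, 7 were at least 2-fold higher than scramble in both KSRP shRNA arrays, and 1 was at least 2-fold lower.

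The RAP1A probe sets at 4.70 and 5.65 and the unnamed probe set at 8.39 stood apart from the rest of the CL1-5 table. A rise of RAP1A messenger RNA read by all its probe sets is argued against by the other RAP1A probe sets, which differed by at most -0.0857. A rise of a form read only by the higher RAP1A probe sets is not excluded by them. Array noise is argued against by the lack of any comparable value in the opposite direction, where the lowest probe set was at -0.832. These probe sets could be reading sequence of the construct; in CL1-0, which lacks it, they differed by at most 0.223, but without probe or construct sequences this cannot be told apart from other causes. No biological explanation beyond RAP1A was tested.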

How the results depend on the processing

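The restriction to RefSeq records, the removal of tied genes, the probe set level, the estimated correlation and the removal of the RAP1A probe sets were chosen after seeing the data. The counts of 0 genes passing limma were 0 under every alternative run. In CL1-0 this says nothing of stability, since that fit called none of its simulated genes. The KSRP status fit called 38% to 96% of its own, but that simulation did not match the spread of the real p-values. The power of that fit on the real values is therefore not known. The unadjusted count in CL1-0 was 1095, with 423 and 173 when genes at 0 in all 3 arrays or identical in the shRNA arrays were left out. With KSRP status it was 218, 141 and 96. KHSRP ranged from -1.34 to -1.58 in CL1-0 and from 1.19 to 1.28 in CL1-5. Genes 2-fold apart in both shRNA arrays numbered 11, and 50 (31 higher, 19 lower) when probe sets were counted; in shKSRP-2 alone there were 84 and in shKSRP-1 alone 436, because fewer conditions apply. The 2 genes in CL1-5 became 1 without the 2 RAP1A probe sets that differed from the others, and 0 on RefSeq records, which hold neither gene's responding probe sets. The 5 lists passing camera in CL1-0 became 4 without probe sets ending in _x_at, where cholesterol synthesis no longer passed. They became 7 without genes at 0 in all 3 arrays and 7 without genes identical in the shRNA arrays, which added let-7 targets and messenger RNAs bound by KSRP (adjusted p of 0.999 and 0.976 for both lists under these filters with an estimated correlation). They became 3 on RefSeq records, 0 with fry and 0 with an estimated correlation. In CL1-0 the estimated correlation also missed a simulated list moved by 1 log2 unit, so that 0 says nothing of stability. Simulated lists were not used to check fry. The 4 lists passing camera with KSRP status became 2 on RefSeq records, 0 with fry and 0 with an estimated correlation. When 1 array was left out they became 0 to 8: 8 without shKSRP-1, 3 without shKSRP-2 (microRNA biogenesis, cholesterol synthesis and oxidative phosphorylation) and 5 without either CL1-5 array. With 1 CL1-5 array the cell line covariate takes up its value, so those 5 rest on CL1-0 alone. Without scramble, where CL1-0 has no control, there were 0, an alternative chosen after seeing the data. For fry and for the other counts without an array the cause was not tested. The microRNA biogenesis median turned to -0.0227 without shKSRP-1 and was 0.26 without shKSRP-2. For single genes, leaving out 1 of the 2 shRNA arrays returns the other's value, which lies within their SD of the mean by construction and shows no stability: FUBP1, at -0.11, was -0.45 without shKSRP-1 and 0.24 without shKSRP-2, and FUBP3, at 0.18, was -0.26 and 0.62. No paired analysis was possible because the sample labels give no pairing of arrays between groups. Offsets, quantile normalisation, the filters on dim probe sets and the control arm comparison were not run, since centred values hold no signal level; leaving an array out of the CL1-0 fits leaves no residual degrees of freedom.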

Other observations

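Except for the ratio of probe set shares, the tests in this part were chosen after the results were seen. Among the genes farthest apart between the shRNA arrays, CSTA, a protease inhibitor, was lower by -3.16 in shKSRP-1 and higher by 2.11 in shKSRP-2, and LAMP3 showed -3.54 and 1.24, INHBE -2.25 and 2.65, MMP10 -1.19 and 2.21, and BST2 -1.44 and 1.498. The unfolded protein and amino acid response list had a median of -0.47 in shKSRP-1 and 0.05 in shKSRP-2. Of its 22 genes, 15 were lower in shKSRP-1 than in both other CL1-0 arrays and 6 were higher. PHGDH, the first enzyme of serine synthesis, was at -2.13 and -0.30, CHAC1 at -1.79 and -0.08 and STC2 at -2.14 and 0.47. DNAJB9, on the same list, went the other way in shKSRP-1, at 1.71 and 1.33. Hypoxia and glycolysis genes had medians of -0.21 and 0.03, with BNIP3 at -2.20 and -0.21. The type I interferon list had medians of -0.15 and 0.09, with members that went both ways in shKSRP-1. IFI35 was at -1.80 and 0.09, and IFI44L at 1.87 and 0.25. Of its 30 genes, 21 were lower in shKSRP-1 than in both other CL1-0 arrays and 5 were higher. GAPDH, a glycolysis enzyme that is on the housekeeping list, was at -0.68 and -0.10. LIN28A and TRIM71 were at 1.67 and 1.52 in shKSRP-2, against -0.33 and 0.09 in shKSRP-1. In the comparison of both shRNA arrays with scramble, camera gave an adjusted p of 0.992 for each of these 3 lists. With shKSRP-1 or shKSRP-2 as the lone array, limma passed 0 genes (4105 and 1579 with an unadjusted p under 0.05), and the 4 and 3 lists called by camera did not include these.

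The shKSRP-1 array also differed by kind of probe set. Within genes, the contrast was the same in direction. Among 4940 genes with both RefSeq and other records, 2.33% had the other records higher by at least 1 log2 unit than the RefSeq records and 0.870% lower, against 0.243% and 0.223% in shKSRP-2.

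For the difference between the shRNA arrays, noise of single probe sets is argued against by a correlation of 0.443 across genes between the differences at 2 probe sets of a gene. Variation of a whole array or its RNA sample would move both probe sets together, so this cannot argue against it. RNA degradation is argued against by the GAPDH and ACTB controls. Their 3′ minus 5′ difference changed by at most 0.152, although both were lower in shKSRP-1. The share of 2-fold higher probe sets was 5.58 times as high on other records or without a symbol as on RefSeq records in shKSRP-1 and 0.624 times in shKSRP-2, a bound fixed before it was computed, which is consistent with more unspliced or non-coding RNA in that sample. Genes annotated as long non-coding do not settle the non-coding part: 0.903% were 2-fold higher in shKSRP-1 against 0.636% of protein-coding genes, a ratio of 1.42 with a 95% interval from 0.914 to 2.21 that covers counting error only. In shKSRP-2 that ratio was 0.244, from 2 of 2657 against 51 of 16516 genes, with an interval from 0.0594 to 1.001. Unequal depletion cannot be told apart, since KHSRP was 0.221 higher in shKSRP-1, within its SE of 0.288 over 4 probe sets. Whether the probe set contrast came from the preparation or from the cells was not tested, nor were separate hairpins.

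Few genes differed in CL1-5. Absence of the fusion is argued against by a KHSRP probe set at 3.44. For the rest, noise of single probe sets predicts that 2 probe sets of a gene do not differ together. Over all probe sets, 2 probe sets of a gene had a correlation across genes of 0.128 in CL1-5, against 0.412 and 0.433 in the CL1-0 arrays. The CL1-5 value was 0.0392 without KHSRP and RAP1A, and 0.0395 without probe sets ending in _x_at. The remaining CL1-5 differences thus showed little agreement between probe sets of a gene, as such noise would give. Small differences shared by probe sets are not excluded.

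KSRP promotes let-7 maturation, so a hypothesis was that let-7 targets would be higher in both shRNA arrays than random lists. The list median lay at the 100th percentile in shKSRP-2 and at the 74.7th in shKSRP-1, where it was 0.00 over members that went both ways. A high percentile in shKSRP-2 was not particular to this list. Type I interferon genes lay at percentile 99.96 there and TGF-beta targets at 99.91, against 0.16 and 63.8 in shKSRP-1. Immediate early genes lay at percentile 99.99 in shKSRP-1 and 100 in shKSRP-2. Of the 21 let-7 targets, 8 were higher in both arrays and 4 lower, against 7 and 6.33 with values placed on the arrays at random. The let-7 list passed camera when genes at 0 in all 3 CL1-0 arrays were left out (adjusted p = 0.0260, and an adjusted p of 0.999 with an estimated correlation) but not over all genes. Whether let-7 targets were higher in both arrays stays open.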
